A study of Arabidopsis thaliana with 6 samples.

How the data were processed

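The series holds 6 ATH1 arrays of sorted Arabidopsis root protoplasts, 3 without and 3 with DEX. Per the labels' protocols, RNA was extracted with TRIzol and biotin-labelled with a kit that primes from the 3′ end of the transcripts. The values were those of the authors' deposited value table, which gives 1 linear intensity per probe set and array. The method that summarised probes to probe sets is not given in the sources used here. The deposited intensity values had a 2% trimmed mean of 500 on every array, so the authors had scaled the arrays to a common mean.

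Because the medians still differed between arrays, each array was scaled to a common median, values were floored at 1, and log2 was taken. Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested. Groups and replicate numbers came from the sample titles. The test was limma (version 3.58.1 in R 4.3.3): lmFit with the group as the only term and eBayes with a trend of variance on level, two-sided, with Benjamini-Hochberg adjustment at 0.05. Errors of a difference are the standard errors of that fit, and errors of a group are SD over 3 arrays.

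Probe sets were named only through the annotation given for the array, with locus identifiers matched to the gene table of TAIR10.1 (GCF_000001735.4). Of the tested probe sets, 13436 had 1 named gene (13286 genes), 503 had several and were left unnamed, 8730 were not listed and 77 were listed with a gene that had no match in the gene table. HRS1 itself is not named in this annotation, so the planned check of its transcript is not reported. The same limit leaves 43 of the 253 loci of the fixed lists measured. Coordinates are not printed, since the build behind the arrays is not given in the sources used here, and the gene table served only for names and for which genes neighbour each other.

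The 23 gene lists were the NIGT1 family, recalled NIGT1 targets, nitrate transport, nitrogen assimilation, nitrate signalling regulators, ammonium and organic nitrogen uptake, phosphate starvation, class III peroxidases and NADPH oxidases, antioxidant enzymes, CC-type glutaredoxins, defence and wounding, heat shock, auxin, cytokinin, abscisic acid, jasmonate and ethylene, root epidermis, ground tissue, vascular tissue, root cap and quiescent centre, photosynthetic genes, cell division and reference genes. With 1 probe set per gene, lists of 3 or more measured members were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over the lists. Measured members were 0 for nitrogen assimilation, nitrate signalling regulators, abscisic acid, jasmonate and ethylene, vascular tissue, root cap and quiescent centre, photosynthetic genes and cell division. A list of 67 heat shock and chaperone loci was added after the data were examined.

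Genes were named by a rule set before the data were examined. It takes the NIGT1 family, the 15 largest rises and the 15 largest falls among probe sets past the threshold without overlap between groups, up to 4 members with the smallest p per list, and NRT2.1, NRT2.4, NRT2.5 and SPX1. A direction with fewer than 10 such genes was filled to 10 by smallest p among genes without overlap, given as values. The further members of the added list were chosen after their values were seen. A gene below the 95th percentile of 27 Bacillus control probe sets on every array of a group has only a bound there, and its ratio is given as at least that of the other group's mean to that percentile.

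The test was tried on simulated data for 22746 probe sets. Among the brightest 25%, 0 of 25 probe sets made 4-fold lower were recovered, 7 of 25 at 8-fold, 10 of 25 at 16-fold and 11 of 25 at 32-fold. Among the next 35% these counts were 0, 0, 1 and 3 of 25, and 0 unchanged probe sets were called. The counts hold for the spread used in the simulation, and its match to the spread of the real arrays was not tested. On the real arrays the 27 probe sets called lower had falls from 4.57-fold to 38.9-fold. The counts are therefore not given as the power of the real comparison. Alternatives covered the replicate block, the scaling, filters on dim probe sets, the variance model, array weights, a floor, thresholds, the set test and each array left out. There were no arrays of DEX-treated protoplasts without HRS1 among those analysed here.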

Results

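Gene expression was measured in Arabidopsis root protoplasts that carried a plasmid from which HRS1 (also called AtNIGT1), a nitrate-regulated transcription factor of the GARP family, was made under the 35S promoter as a fusion to the hormone-binding part of the glucocorticoid receptor. Such a fusion is held in the cytoplasm until dexamethasone (DEX), a synthetic glucocorticoid, lets it enter the nucleus. All protoplasts were given nitrate and 35 µM cycloheximide, which blocks protein synthesis. In 3 samples 10 µM DEX was added and in 3 it was not. Transfected cells were sorted by their red fluorescent protein, and the RNA of each sample was measured on 1 ATH1 array, so that 6 arrays and 22746 probe sets entered the comparison. The median deposited intensity was 71.8, 66.3 and 87.7 on the −DEX arrays and 79.1, 92.9 and 85.0 on the +DEX arrays. With 3 arrays per group, their number limits the precision: the median standard error of a log2 difference was 0.83 among the brighter 60% of probe sets and 1.34 among the dimmest 40%. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

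The comparison of +DEX with −DEX asks which transcripts change when HRS1 is let into the nucleus while new protein synthesis is blocked. Of the 27 probe sets that fell with DEX, 12 had a named gene, and 9 of these 12 encode small heat shock proteins or partners of the larger chaperones. AT5G48570, an FKBP-type peptidyl-prolyl isomerase known to work with HSP90, fell by 4.56 ± 0.48 on the log2 scale (SE; limma adjusted p = 0.0038). Its log2 intensity was 15.01 ± 0.84 (SD, n = 3) on the −DEX arrays and 10.45 ± 0.78 (SD, n = 3) on the +DEX arrays. AT1G52560, a small heat shock protein, fell by 5.28 ± 0.86 on the log2 scale, or 38.9-fold (limma adjusted p = 0.024), but this size rests on the array of +DEX replicate 1, where it lay at background. Without that array it fell by 3.91 (15.1-fold), and without +DEX replicate 2 it fell by 6.11 (69.0-fold). In all, limma called 27 probe sets lower with DEX and 0 higher at an adjusted p under 0.05.

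**Figure D1:**
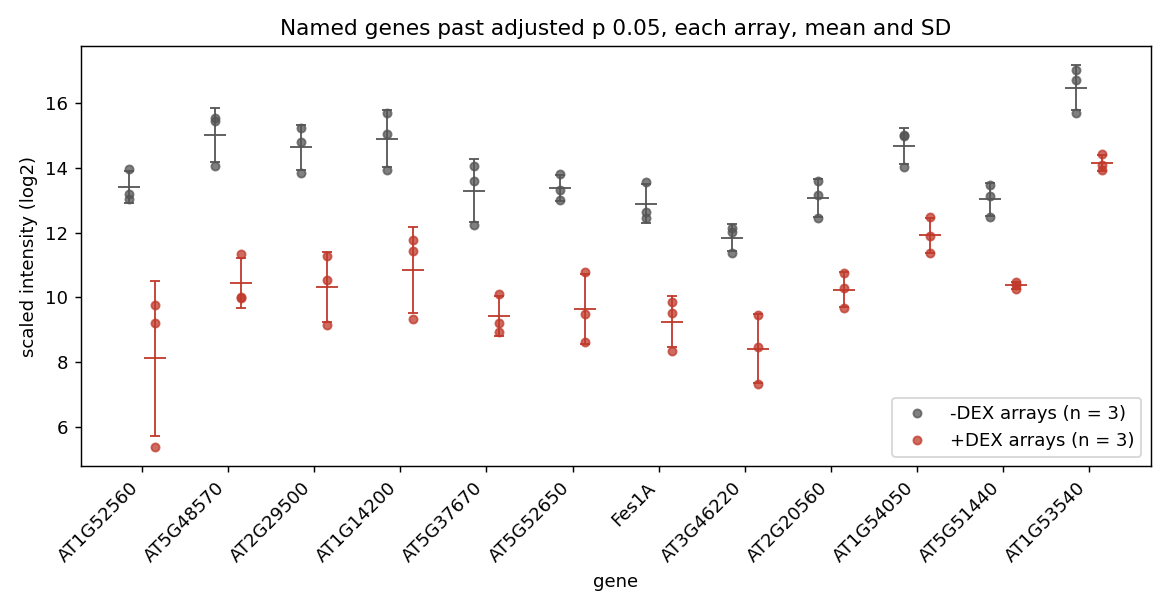
Scaled intensity (log2, vertical axis) of the 12 named genes past the threshold (horizontal axis), with 1 point per array, the −DEX arrays in grey and the +DEX arrays in red, and with group means and SD as bars (n = 3). In each of the 12 genes the 3 +DEX points lie below the 3 −DEX points.

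The other 15 of the 27 probe sets had no single named gene in the annotation used here, so the description of genes covers the 12. Small heat shock proteins made up 6 of them. AT2G29500, of the cytosolic class I, fell by 4.30 ± 0.52 (log2, SE), from 14.63 ± 0.71 to 10.33 ± 1.08 (SD, n = 3 each). AT5G37670 fell by 3.88 and AT1G54050 by 2.77. AT1G53540 had the brightest probe set of the 12 and fell by 2.32 ± 0.34, from 16.47 to 14.15, so that it remained bright with DEX. AT5G51440, whose protein is placed in mitochondria, fell by 2.66. Co-chaperones were the next group. Fes1A, a nucleotide exchange factor of HSP70, fell by 3.64 ± 0.51 (12.5-fold), and AT2G20560, a J-domain protein, fell by 2.83 ± 0.45 (7.09-fold).

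The remaining 3 named genes were AT1G14200, which encodes a RING-type zinc finger protein and fell by 4.05 (without +DEX replicate 1 it fell by 3.29, adjusted p = 0.073), AT5G52650, which encodes a protein of the small ribosomal subunit and fell by 3.73, and AT3G46220, which fell by 3.42 and had an adjusted p of 0.036. In the gene table of assembly TAIR10.1, AT5G52650 lies next to AT5G52640, a gene of the HSP90 family. The protein-coding gene next to AT3G46220 is HSP17.4, a small heat shock protein. Over all 27 probe sets the fall ranged from 4.57-fold to 38.9-fold (4.20-fold to 20.4-fold without +DEX replicate 1), and in each of them every +DEX array lay below every −DEX array. Values without overlap between the groups occurred in 12.5% of all tested probe sets, against 10% by chance.

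**Figure D2:**
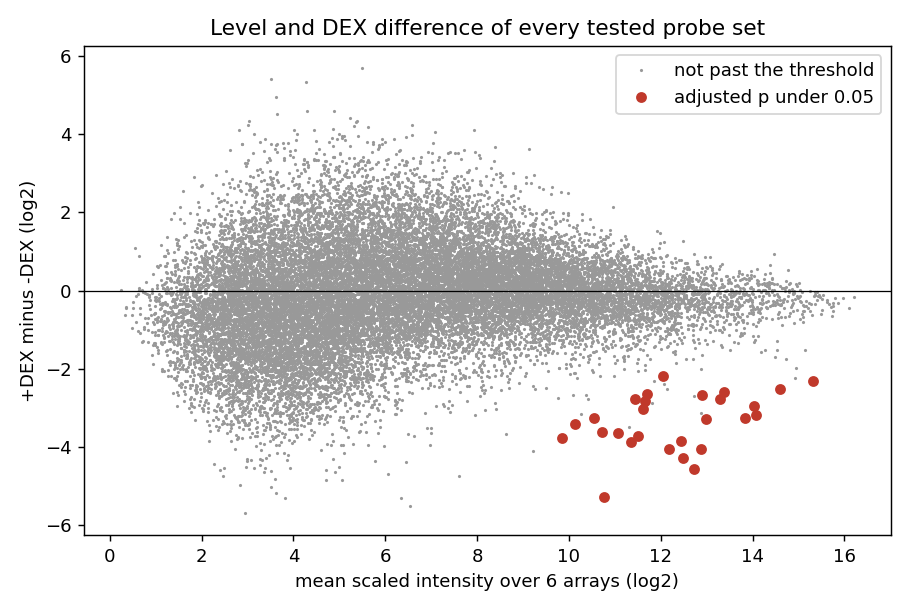
Difference between +DEX and −DEX (log2, vertical axis) against the mean scaled intensity over 6 arrays (log2, horizontal axis) for 22746 probe sets, with the 27 past an adjusted p of 0.05 in red. The red points all lie below 0 and at a mean level of 9.84 or higher, and the scatter of the grey points is wider at low intensity.

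These calls rest on the variance model and on single arrays. With eBayes fitted without a trend of variance on level, limma called 0 probe sets lower, with a smallest adjusted p of 0.49, and with values floored at a log2 of 5 it also called 0. Leaving out −DEX replicate 1, 2 or 3 gave 12, 0 or 46 probe sets lower, and leaving out +DEX replicate 1 or 3 gave 3 or 4. All 27 kept a negative difference each time, but without overlap between the groups this could not have come out otherwise. At an unadjusted p under 0.05 there were 1500 probe sets, against 1137 expected with no difference and 1637 in a split of the arrays that mixes the groups. Of the 1500, 933 were lower and 567 higher, but the balance turned with the scaling, to 710 lower and 784 higher after quantile normalization and 683 lower and 825 higher as deposited, and to 752 lower and 781 higher without −DEX replicate 2.

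No rise passed the threshold (smallest limma adjusted p of a higher probe set, 0.12). The 10 named genes with the smallest p among higher values without overlap are given as values only. M17, a transcript of seed maturation, had a mean of 2.64 ± 1.02 without and 8.33 ± 0.70 with DEX (SD, n = 3 each). On all 3 −DEX arrays its intensity lay under the 95th percentile of control probe sets for Bacillus RNA, so its ratio is given as at least 4.80-fold, the +DEX mean set against the mean of that percentile over the 3 −DEX arrays (6.07). NRPB12, a subunit of RNA polymerases, had a difference of 2.53 ± 0.55, from 8.56 ± 0.54 to 11.09 ± 0.55 (SD, n = 3 each; adjusted p = 0.20). AT4G00990 had a mean of 6.71 without and 10.02 with DEX, and lay above that percentile on 1 of 3 −DEX arrays. AT5G67490 did so on 1 of 3, with means of 5.69 and 8.85, and AT3G29270 on 2 of 3, with means of 5.88 and 9.98. The others were AT3G19790 (2.15), AT3G19515, AT3G19780, AT4G19550 and AT4G07700, the last 4 of which lay under that percentile on every −DEX array. AT4G07700 lay under it on all 6 arrays, so its difference is one of background.

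A list of 67 heat shock, chaperone and heat shock factor genes was written after the falls had been seen, to count how far they extended, and so is not independent evidence of their direction. Of its 18 measured members, 16 had a lower and 2 a higher mean with DEX, and the median log2 difference was −2.73. Past the threshold over all probe sets were 9 of the 18, and 15 were past it when adjusted over the list alone. The 15 include those 9, whose falls had prompted the list. Members just outside the threshold over all probe sets were AT3G09440 (−2.39 ± 0.46) and Hsp70-2 (−2.66 ± 0.51), both of the HSP70 family, and Hop3 (−2.69 ± 0.52), which links HSP70 to HSP90, each with a limma adjusted p of 0.085. Hop1 had a difference of 0.57 ± 0.53. AT4G21870 lay under the percentile of the Bacillus controls on every −DEX array, with means of 3.23 without and 3.99 with DEX. The set test camera gave the list p = 4.4e-36 with a preset correlation of 0.01, and p = 0.0082 with an estimated correlation. Both include the 9 called genes, so neither these p-values nor the list median are independent evidence of a fall. The mean over the list was 12.53, 12.72 and 12.01 on the −DEX arrays and 9.03, 10.32 and 9.56 on the +DEX arrays. The array of −DEX replicate 1 stood apart from the rest, with a mean Spearman correlation with the other arrays of 0.708, against 0.777 to 0.822 for the others. Its ratio of 3′ to 5′ signal was the highest for the ubiquitin control, 11.1 against 5.21 to 8.90. For the GAPDH control that ratio was the lowest, 0.75 against 0.91 to 1.24. Without this array the list median was −2.59.

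**Figure D3:**
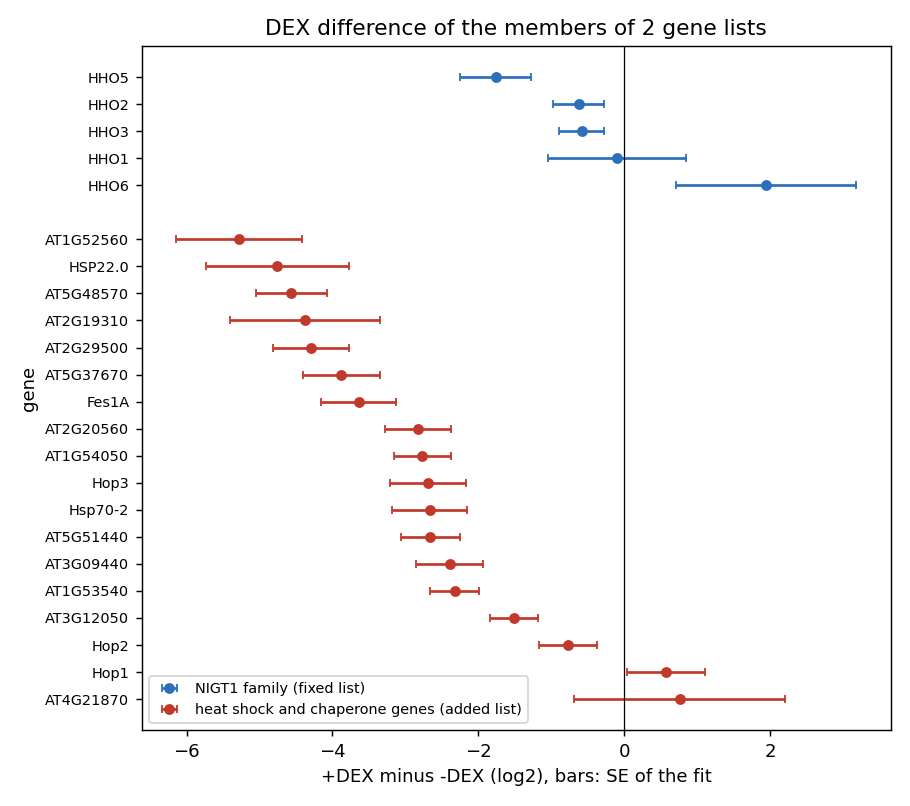
Difference between +DEX and −DEX (log2, horizontal axis) with its SE for the 5 measured members of the NIGT1 family and the 18 measured members of the added list of heat shock and chaperone genes (vertical axis). Of the 18, 16 lie below 0. Of the 5, HHO5 lies farthest below 0, at −1.76, and HHO6 above 0, at a value that rests on arrays at background.

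The NIGT1 family, to which HRS1 belongs, was compared to ask whether related genes follow it. None of its 5 measured members passed the threshold over all probe sets, and 1 did when adjusted over the list alone. That member was HHO5, with a log2 difference of −1.76 ± 0.49 (SE; limma adjusted p = 0.55 over all probe sets, 0.014 over the list alone), from 12.08 ± 0.90 to 10.31 ± 0.09 (SD, n = 3 each). HHO2 and HHO3 differed by −0.63 ± 0.35 and −0.58 ± 0.31, and HHO1 by −0.10 ± 0.95. HHO6 had means of 4.31 without and 6.26 with DEX, but lay above the 95th percentile of the Bacillus controls on 1 of 3 −DEX and 2 of 3 +DEX arrays, and its difference of 1.95 ± 1.24 became 0.995 with values floored at a log2 of 5. The family's median was −0.58 (camera adjusted p = 0.31, and adjusted p = 0.55 with an estimated correlation), and it shrank to −0.24 after quantile normalization and −0.39 as deposited. HHO2 and HHO3 were then at −0.26 and −0.24, and at −0.43 and −0.39.

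Of the nitrate transport list, 1 of 20 loci was measured, NRT2.5. Of the genes recalled as NIGT1 targets, 4 of 9 loci were measured. These were HHO1, HHO2, HHO3 and NRT2.5, a high-affinity nitrate transporter, with a median of −0.61 (camera adjusted p = 0.31). NRT2.5 lay under the 95th percentile of the Bacillus controls on every array, with means of 3.77 without and 2.74 with DEX, so its difference is one of background. NRT2.1, NRT2.4 and SPX1 are not named in the annotation used here and have no value. Of the genes for organic nitrogen and ammonium uptake and systemic nitrogen signalling, CEPD1 lay under that percentile on every array. CEPD2 lay under it on every −DEX array, with means of 2.32 without and 4.57 with DEX, and no ratio is given (limma adjusted p = 0.77). For the phosphate starvation response, LPR2, a multicopper oxidase of root phosphate sensing, differed by −0.75 ± 0.84, and its relative LPR1 lay under the percentile on every array.

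Redox genes followed no single direction. Of 10 measured class III peroxidases, 4 had a positive and 6 a negative difference, with a median of −0.07 (camera adjusted p = 0.99). Examples were PRX71 (0.61 ± 0.42) and PRX52 (−0.93 ± 0.90). PRX56 lay above the percentile of the Bacillus controls on 1 of 3 arrays in each group, and PRX44 lay under the percentile on every array. Of 10 CC-type glutaredoxins, 3 were positive and 7 negative, with a median of −0.64 (camera adjusted p = 0.66), but 6 of the 7 negative members, GRXS8, GRXS1 and GRXS5 among them, lay under the percentile on every array, so that the median is mostly one of background. GRXS6 lay above it on 1 of 3 −DEX arrays, with means of 5.20 without and 6.76 with DEX (adjusted p = 0.81). The glutathione transferase GSTU25 differed by −1.79 ± 0.84. Its values overlapped between the groups, at 7.77, 11.62 and 9.80 on the −DEX and 8.22, 8.16 and 7.44 on the +DEX arrays, with −DEX replicate 2 the highest.

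The measured stress and hormone genes of the fixed lists also stayed short of the threshold. Outside heat shock, these were 3 of 14 loci for defence and wounding, 3 of 10 for auxin and 1 of 10 for cytokinin. For abscisic acid, and for jasmonate and ethylene, 0 were measured. For defence and wounding, ZAT10 and WRKY53 differed by 0.11 and −0.14, and PDF1.2 lay under the percentile on every array (camera adjusted p = 0.99 for the 3). For auxin, GH3.3, an enzyme that conjugates the hormone, differed by 0.41 ± 0.30, and LBD16 by −0.78 ± 0.76 (camera adjusted p = 0.99). The list's median of 0.36 is the value of LBD29, which lay under the percentile on every array, and its mean was −0.0036. The cytokinin response regulator ARR15 differed by −0.44 ± 0.86. The heat shock list fixed before the data were examined had 1 measured member, HSP22.0 of the endoplasmic reticulum, with a mean of 9.97 without and 5.22 with DEX (limma adjusted p = 0.13 over all probe sets). It lay above the percentile on 1 of 3 +DEX arrays, and its difference was −4.76 ± 0.98 as measured and −4.16 with values floored at a log2 of 5. Adjusted over the list alone it counts as 1 call, but with 1 member no adjustment takes place, and the value is the unadjusted limma p of 0.00025.

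Cell type markers were too few for a statement on cell composition. EXPA7 of root hairs and CO2 of the cortex both lay under the percentile of the Bacillus controls on every array. The reference genes SAND, UBC21 and TIP41 differed by 1.05 ± 1.24, −0.35 ± 0.70 and −0.28 ± 0.61, with a negative median of −0.28 and a positive mean of 0.14 (camera adjusted p = 0.99). SAND lay above the percentile on 2 of 3 −DEX arrays. Of the 23 lists fixed before the data were examined, 7 had 3 or more measured members and could be tested, 8 had 1 or 2 and 8 had 0. Past an adjusted p of 0.05 were 0 of the 7 by camera with a preset correlation, 0 with an estimated correlation and 0 by fry.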

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

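The values as deposited, the joint filter and variance setting, the covariate and the added heat shock list were chosen after seeing the data, and the other settings before. In every setting run, 0 probe sets were higher at an adjusted p under 0.05, all 27 lower probe sets kept their sign, and the added list kept a median between −2.48 and −3.12. The call is less stable than the sign. Probe sets lower numbered 0 without the variance trend, 0 with a floor at a log2 of 5, 0 without the dimmest 60% and the trend together, and 45 with the hybridisation control level as a covariate. Leaving out single arrays gave 0 to 46, the 0 without −DEX replicate 2. At an unadjusted p under 0.01 there were 211 lower and 77 higher, where a share of 0.01 of the 22746 tested is expected with no difference. This threshold was counted with the main scaling only. At an unadjusted p under 0.05 the balance turned with the scaling, from 933 lower and 567 higher to 710 and 784 after quantile normalization and 683 and 825 as deposited, and to 752 and 781 without −DEX replicate 2. The cause was not tested. The other settings gave 21 to 37. The median difference over all probe sets was −0.10 as scaled, 0.01 after quantile normalization and 0.09 as deposited. The HRS1 transcript could not be followed because the annotation used here does not name it.

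Deviations of arrays with the same replicate number correlated by 0.018, 7.7e-06 and 0.042, and those with different numbers by −0.033 to 0.0080. These values show no clear pairing but do not exclude one, and the labels do not state any. With the number as a block, 33 probe sets were lower, 26 of them among the 27, and 0 lists passed.

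Lists past the threshold numbered 0 throughout, except 1 (the NIGT1 family) without the dimmest 60% and the trend, where 3 lists were tested instead of 7. The list tests did not take up the eBayes settings, so that 1 list came with the filter alone. The 0 under the eBayes settings only repeats the main test. Signs of list directions are those of the median. Only values that were not called turned. Under quantile normalization the peroxidases were at 0.11 and WRKY53, also the median of its list, at 0.21. Without the dimmest 40% the peroxidases were at 0.12 (the same without the dimmest 60%) and the glutaredoxins at 1.05. As deposited the peroxidases were at 0.12, WRKY53 and its list at 0.049 and HHO1 at 0.10. With single arrays left out, the peroxidases ranged from −0.64 to 0.10, PRX52 from −2.09 to 0.11, WRKY53 and its list from −0.48 to 0.19, HHO1 from −0.46 to 0.58, and SAND from −0.27 to 1.92. LBD29, at background on every array, ranged from −0.024 to 0.96 and the auxin list from −0.024 to 0.58. TIP41 ranged from −0.73 to 0.094 and the reference genes from −0.32 to 0.094. The cause was not tested. Signal over background limits the dim genes: 7606 probe sets lay above the 95th percentile of the Bacillus controls on all 6 arrays.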

Other observations

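Of 30 gene families scanned after the data were examined, plastid-encoded transcripts had a positive median difference with DEX, 0.69 over 69 genes. Of the 69, 13 were negative and 0 passed the threshold (camera adjusted p = 2.6e-06, but adjusted p = 0.83 with an estimated correlation and fry adjusted p = 0.47). Their mean was 7.47, 8.45 and 8.71 on the −DEX arrays and 9.05, 8.70 and 8.92 on the +DEX arrays, and without −DEX replicate 1 the median was 0.30. The TBL genes, a family that includes acetyltransferases of cell wall polysaccharides, had a median of −1.45, with 18 of 22 negative (camera adjusted p = 0.032, fry adjusted p = 0.023). With an estimated correlation the camera p was 0.028 unadjusted and 0.83 adjusted over the 30 families. The mean level over the TBL family was 4.69. This lay above the mean of the Bacillus controls on every array (2.24 to 4.24), but under their mean 95th percentile (5.76). Of 10000 random lists matched on level, 6 had a median as low. The background was also lower with DEX on average, but its array means overlapped between the groups. Of the 27 Bacillus control probe sets, 20 had a lower +DEX mean, with a median difference of −0.74. The dimmest 40% of probe sets had a median of −0.48. The Bacillus mean of −DEX replicate 3 (3.05) lay below those of +DEX replicate 1 (3.39) and +DEX replicate 3. The probe sets share the same arrays, so the count of 20 does not measure the spread between arrays. Among 47 UGT genes, which transfer sugars to small molecules, 34 were negative, with a median of −0.69. The camera adjusted p was 0.12, or 0.83 with an estimated correlation, and the fry adjusted p was 0.39. A median as low occurred in 26 of 10000 random lists matched on level. UGT73B4 and UGT73B5, chosen after their values were seen, differed by −1.75 and −1.98 and did not pass the threshold. The signs of these 3 medians held under quantile normalization, as deposited and with each array left out, but their sizes did not: the TBL median was −0.74 without +DEX replicate 1 and the UGT median −0.36 without −DEX replicate 1.

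Of the tests on the heat shock genes and their neighbours, only the one over neighbours of all kinds was set down before its result was seen. The lower level of heat shock and chaperone genes with DEX was set against 3 explanations. Unequal hybridisation between arrays was tested with the level of the bacterial hybridisation controls as a covariate. The list median was then −2.74, against −2.73 without it (camera p = 0.029 with an estimated correlation, on the list written after the falls were seen). The control levels overlapped between the groups, at 14.48, 13.95 and 13.67 (log2, as deposited) on the −DEX arrays and 14.35, 13.83 and 14.09 on the +DEX arrays. A covariate so balanced could hardly move the median, so the fit adds little to that overlap. A higher background on the −DEX arrays was argued against by the level of the genes: their median −DEX mean lay 6.57 (log2) above the highest 95th percentile of the Bacillus controls. DEX acting through the receptor part of the fusion, which unliganded is known to bind HSP90, cannot be told apart from an effect of HRS1 in the nucleus, because 0 of the arrays had DEX without HRS1. Handling that differed between the groups and a direct or indirect action of HRS1 also stay open and were not tested.

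The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 27 probe sets past the threshold, more than the 0 of each other split, so 1 of the 10 reached it. At an unadjusted p under 0.05 the order differed: the real split had 1500 probe sets, and the split that sets −DEX replicates 1 and 2 with +DEX replicate 1 against the rest had 1637. For the added list, 1 of the 10 splits had a median as far from 0 as the real one, whose size was 2.73. The highest of the others was 1.63. That list was written after the falls in the real split were seen, so its first place was favoured by construction and says nothing about chance. For the fixed lists, the real split had 0 past the threshold, the highest other had 1, and all 10 reach a count of 0 by construction, so this says nothing about chance.

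Of the 12 named genes that fell, 1 that is not on the added list, AT5G52650, lies beside a listed heat shock gene in the full gene table. Over protein-coding genes alone there are 2, AT5G52650 and AT3G46220. A candidate explanation is that neighbours of heat shock genes fall with them. Over the gene table in full, the 45 other measured neighbours of the 67 listed loci had a median of −0.20, and 1923 of 10000 random lists matched on level were as low or lower, and over protein-coding genes alone, an order chosen after that result, the 54 others had −0.23 and 1116 of 10000, with 4 lower and 1 higher at an unadjusted p under 0.05 (4 and 0 over the full table). These do not exclude it, although the first met the bound set for exclusion: 18 of the 67 loci were measured, so most of these neighbours adjoin genes not known to have fallen. Beside the 15 listed genes measured as lower at an unadjusted p under 0.05, 12 other neighbours had a median of −0.28 (95% sign interval −1.08 to 0.81; 3103 of 10000 lists), too wide to decide, and transcription running on from a heat shock gene was not tested.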
